A study of Homo sapiens with 6 samples.

How the data were processed

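The study measured DNA break ends by BrITL, in which the 3' ends of broken DNA in permeabilised cells are labelled with a biotin-carrying chain terminator, pulled down on streptavidin beads and sequenced. Per the labels, MDA-MB-231 cells received either DMSO or 0.5 µM VE-822 with 0.2 µM aphidicolin for 9 h. Each condition had 2 pull-down libraries and 1 input library, so 6 samples fell into 4 groups. The labels number the pull-down libraries of both conditions as replicates 1 and 2 and do not say whether these came from separate cultures.

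Per the submitters' processing notes, the tools named were bcl2fastq 2.17.1.14, STAR 2.5.2a, SAMtools 0.1.19, Picard 1.141 and MACS2 2.1.0, and the builds named were hg19 and mm10. Their settings are not given in the sources used here. The authors deposited 1 peak list per condition, each holding the regions called on the pooled pull-down libraries against the condition's input, as the peak names state. All regions on chromosomes 1 to 22, X and Y fitted within the hg19 chromosome lengths, and positions are given in hg19, counted from 1. The deposited fold enrichment of a peak is the ratio of its pull-down pileup to its local background. The deposited significance columns are −log10 of the p-value and of the q-value. The deposited score is an integer used here for nothing beyond checking the files. Each peak's deposited summit offset, a unit of its own (bases from the start of the peak), gave the summit position. Fold and −log10 values are the authors', belong to separately called lists, and were used to describe, rank or filter peaks within 1 list, except where both lists were kept to a common threshold (a −log10 q of at least 10, a fold of at least 5, or a lowest −log10 p or fold of the DMSO list) to compare list lengths and overlap. Such thresholds do not put the values of the lists on 1 scale.

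The lists give no read totals. Reads behind each summit were recovered from the fold and the p-value, with MACS2's formulas as they are generally known (fold as pileup plus 1 over background plus 1, and a Poisson tail for p). Every peak of both lists came out at a whole number of pull-down reads (100%, tolerance 0.02 reads). On simulated peaks of both list sizes (1100 and 380 peaks) the same procedure returned 100% of the reads. The treated pull-down reads had been scaled by 0.567 to the input, and the DMSO pull-down reads were unscaled. The genome-wide mean pileup behind the peaks was 5.13 reads in the treated pull-down and 1.64 in the DMSO pull-down, a ratio of 3.13. Summits held 27 to 140 reads in the treated list and 15 to 156 in the DMSO list, which sets the counting precision of each value. Libraries were amplified by PCR, so intervals cover counting error only. The shortest region was 78 bp in both lists and was taken as the fragment length of the caller.

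Regions of the lists were shared when they overlapped by at least 1 bp. Treated-only and DMSO-only regions are those without such an overlap, which is a statement about the deposited lists and not about the absence of reads. Overlap, distances and shares along chromosomes were compared with 1000 random placements of the same regions within their chromosomes, the width kept, which permutes positions and is called a permutation p in the text. Placement did not avoid assembly gaps, where no region can be called, and chromosome and band lengths include them. Gaps gather at centromeres, in heterochromatin and at chromosome ends, and distances to the chromosome end are affected to an extent not measured. A deficit of regions near centromeres or in heterochromatin cannot be told apart from gaps by these placements. Its p-values are therefore not used. The smallest p these placements can give is 0.000999 one-sided and 0.002 two-sided. Fold values of shared and treated-only regions were compared with a two-sided permutation test of the medians with 100000 resamples. Counts per chromosome and per cytogenetic band were compared with length by exact binomial tests with Benjamini-Hochberg adjustment, over 24 chromosomes or 862 bands. These tests and the random placements treat regions as independent. Regions lay in clusters, so the p-values for chromosomes, bands, gene lists and gene density are too small, to an extent not measured. The same holds for permutation tests between sets of regions. The chi-square statistic over chromosomes was set against 10000 multinomial draws. Intervals of shares are 95% exact Clopper-Pearson intervals. On simulated lists the overlap test passed 0.05 in 0 of 20 random placements and found all of 30 planted shared regions, and the chromosome test made 0 calls on a random list.

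Cytogenetic bands of hg19 came from the R package circlize 0.4.16 (R 4.3.3). The gene table used is of assembly GRCh38.p14, so no gene coordinate was set against a region. Genes were assigned to bands of their own assembly, regions to bands of hg19, and the band names, identical for all 862 bands, joined them. Band assignment is coarse, since a band spans several Mb and a region in it need not lie in or near the gene. The remaining steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

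Designs, alternatives and 7 gene lists were fixed before the data were examined. The regions named are, by that rule, the 12 treated-only, 6 shared and 6 DMSO-only regions with the highest fold in their list, and at most 4 genes per gene list, ranked by the highest treated fold in their band. The rule also asked for the genes with most treated-only summits, and the bands with most such summits stand in their place. Sequence composition and repeats at summits, and the position of summits relative to exons, introns and intergenic sequence, were planned and not analysed here, because a genome and annotation of hg19 were not used here. Comparisons by band, by stain, by distance to centromeres and by gene density, and the band form of the gene lists, were chosen after the files were examined. Regions outside chromosomes 1 to 22, X and Y (10 treated and 52 DMSO) were left out of the comparisons. The pooled lists hold no spread between libraries, so a difference in list length has no test across libraries. Alternatives tried were stricter and matched thresholds, other definitions of sharing, local shuffles, merged neighbours, lists without heterochromatic bands or without a single band, and lists without chromosome ends.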

Results

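The data map sites of DNA breakage in MDA-MB-231 cells, a human triple-negative breast cancer line. Cells were exposed for 9 h either to DMSO or to ATRi+APH, the ATR inhibitor VE-822 (0.5 µM) with a low dose of the DNA polymerase inhibitor aphidicolin (0.2 µM). ATR is the kinase that stabilises stalled replication forks, and the design asks where breaks arise when forks are slowed while ATR is inhibited. Break ends were captured by BrITL in 2 libraries per condition and sequenced along with 1 input library per condition. The files hold 1 pooled list of enriched regions per condition, so no value below has a replicate spread. The pooled treated pull-down was deeper than the DMSO pull-down, with a genome-wide mean pileup of 5.13 against 1.64 reads (recovered from the peak statistics).

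The list of ATRi+APH cells held more regions than that of DMSO cells, and its regions were wider. There were 1133 treated regions, 1123 of them on chromosomes 1 to 22, X and Y, and 381 DMSO regions, 329 of them on those chromosomes. Treated regions covered 318 kb with a median width of 207 bp (quartiles 115 and 362), and DMSO regions covered 124 kb with a median width of 159 bp (quartiles 100 and 299). The authors' fold enrichment had a median of 4.23 (quartiles 4.04 and 4.61) in the treated list and 6.06 (quartiles 3.64 and 7.86) in the DMSO list, values that are not on 1 scale because the lists were called separately. The lists reach down to different levels of significance, a −log10 p of 6.41 in the treated list and 10.5 in the DMSO list. At or above the latter level on chromosomes 1 to 22, X and Y there were 119 treated and 329 DMSO regions, so the order of the list lengths turned.

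Over the whole lists, most regions of ATRi+APH cells had no counterpart in the DMSO list, while most of those with a −log10 q of at least 10 had one. Of the 1123 treated regions, 58 (5.16%, 95% exact interval 3.94 to 6.63) overlapped a DMSO region, and of the 329 DMSO regions, 50 (15.2%, interval 11.5 to 19.5) overlapped a treated region. This left 1065 treated-only and 279 DMSO-only regions. There were 35 treated regions past that threshold, of which 28 (80%, interval 63.1 to 91.6) overlapped a DMSO region, and 25 (71.4%, interval 53.7 to 85.4) overlapped 1 of the 168 DMSO regions past the same threshold. Of the 119 treated regions at or above the lowest −log10 p of the DMSO list, 38 (31.9%, interval 23.7 to 41.1) did. Random placement of the DMSO regions gave a mean of 0.073 overlapping regions and at most 2 (1-sided permutation p = 0.000999, the smallest that 1000 placements can give).

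The shared regions were mainly subtelomeric. Of the 58 shared regions, 37 (63.8%, exact interval 50.1 to 76.0) had their summit within 100 kb of a chromosome end, where random placement put 0.088 on average (permutation p = 0.002, the smallest these placements can give). They fell on 18 of the 48 chromosome ends, and their median distance to the end was 0.0286 Mb. The background at shared regions near ends had a median of 1.00 times the genome background, the lowest value that the recovered background can take. Single regions lay higher, such as those with summits at 249240234 on chromosome 1 (5.16 times) and 11580 on chromosome 5 (4.13 times). By fold in the treated list the first 6 lay at 5p15.33 (chromosome 5, 10398 to 10545, fold 20.6), 2q37.3 (chromosome 2, 243153717 to 243154161, fold 13.3), 21q22.3 (chromosome 21, 48119734 to 48119886, fold 12.7), 1q44 (chromosome 1, 249239605 to 249239820, fold 11.7), 18p11.32 (chromosome 18, 11147 to 13182, fold 10.8) and again 21q22.3 (48119240 to 48119525, fold 9.54). Each of these summits lay between 10.1 and 45.5 kb from the end of the hg19 chromosome. Among treated-only regions 4 (0.376%, interval 0.102 to 0.959) were within 100 kb of an end, against 1.43 by random placement (permutation p = 0.122), and among DMSO-only regions 17 (6.09%, interval 3.59 to 9.58) were, against 0.492 (permutation p = 0.002).

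Within the treated list the shared regions were more enriched than the treated-only regions. Their median fold was 5.54 (quartiles 4.35 and 7.10, n = 58) against 4.22 (quartiles 4.04 and 4.60, n = 1065), a log2 difference of 0.39 (permutation test, p = 1e-05, the smallest that 100000 resamples can give). Without regions within 100 kb of a chromosome end the difference was 0.02 (permutation p = 0.479, 21 shared regions left), so no difference was detectable away from the chromosome ends. Median widths were 206 and 207 bp.

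**Figure D1:**
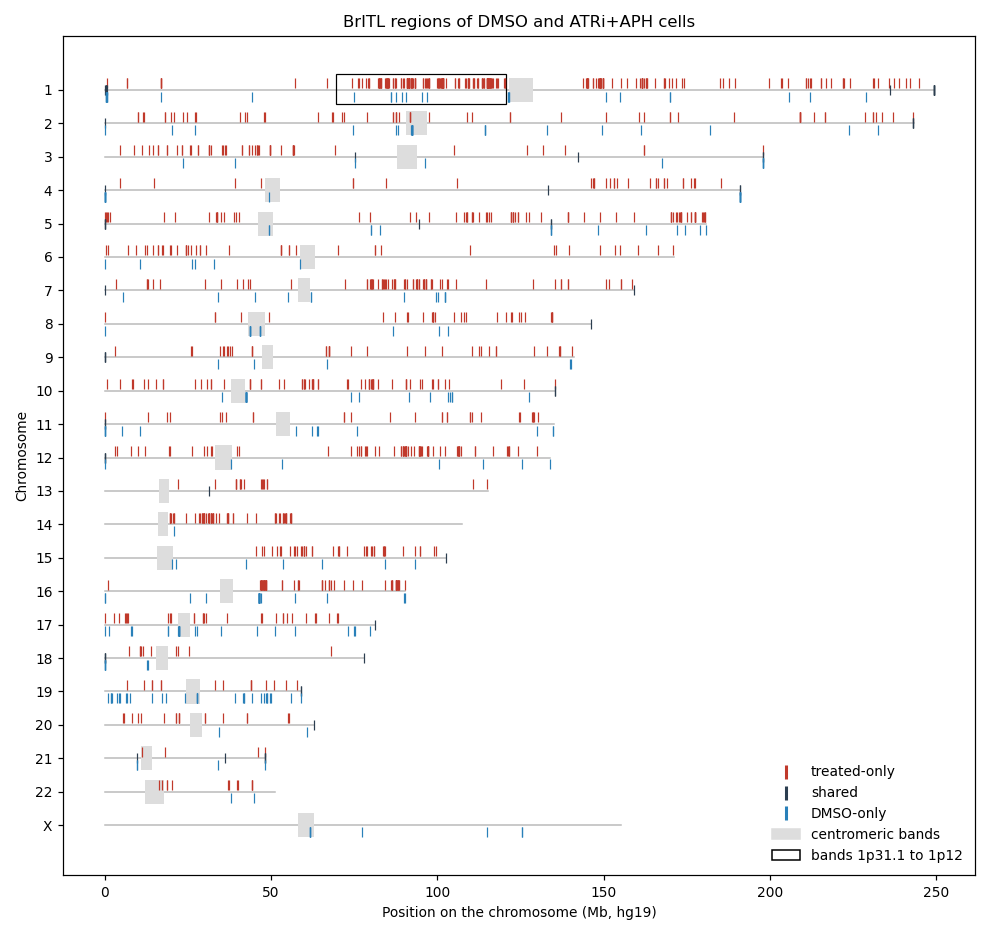
Positions of treated-only, shared and DMSO-only regions (ticks) along chromosomes 1 to 22 and X in Mb of hg19, with centromeric bands in grey and bands 1p31.1 to 1p12 outlined. Shared ticks sit mostly at chromosome ends, 144 of the 1065 treated-only ticks fall within the outlined bands, and no treated tick lies on chromosome X.

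Treated-only regions were spread unevenly over the chromosomes, with a strong excess on chromosome 1. Chromosome 1 held 234 of them (22%, exact interval 19.5 to 24.6), 2.73 times the share expected from its 8.05% of the genome length (exact binomial test, adjusted p = 1.72e-43). Chromosomes 16, 12, 14, 10 and 7 were also above expectation, at 1.8, 1.56, 1.54, 1.39 and 1.35 times (exact binomial test, adjusted p from 0.000171 to 0.0161). Chromosomes 2, 4, 8, 11, 13, 18 and 21 were below it, at 0.717 to 0.242 times (exact binomial test, adjusted p from 9.31e-06 to 0.0125). Chromosome X held 0 regions, where 5.02% of the length lies (exact binomial test, adjusted p = 3.43e-23). Chromosome Y, with 1.92% of the length, also held 0. Whether these cells carry a Y chromosome was not measured, so no conclusion is drawn from its count. The chi-square statistic over chromosomes was 482, above the highest of 10000 draws by length (57.7, p = 1e-04, the smallest possible). Copy number was not measured here. Where the local background equalled the genome background (403 treated-only regions), chromosome 1 held 11.9% (exact binomial p = 0.00759).

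DMSO regions followed another order. Chromosome 19 held 34 of the 329 (10.3%, interval 7.26 to 14.1), 5.41 times the expectation from length (exact binomial test, adjusted p = 7.76e-14). Chromosomes 17 and 16 stood at 2.78 and 2.40 times (exact binomial test, adjusted p = 0.000106 and 0.00105), and chromosomes 6, 13 and 14 were below expectation at 0.330, 0.0817 and 0.0877 times (exact binomial test, adjusted p = 0.00604, 0.00084 and 0.00105). Chromosome X held 8 DMSO regions, 0.485 times the expectation (exact binomial test, adjusted p = 0.0798).

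**Figure D2:**
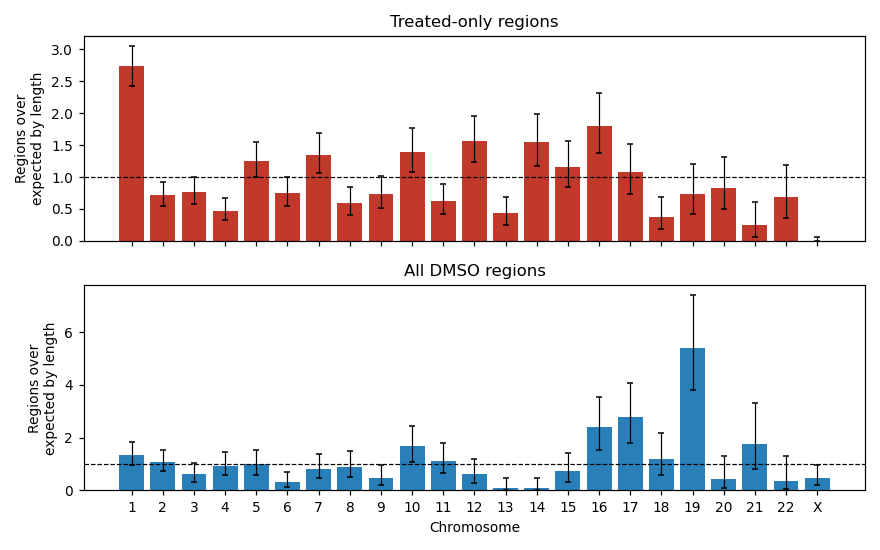
Number of regions per chromosome over the number expected from chromosome length, for treated-only regions (upper panel) and all DMSO regions (lower panel), with 95% exact binomial intervals as error bars and a dashed line at 1. Chromosome 1 stands at 2.73 in the upper panel and chromosome 19 at 5.41 in the lower panel.

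The excess on chromosome 1 was densest on the proximal short arm. Bands 1p31.1 to 1p12 (69700001 to 120600000, 50.9 Mb) held 144 treated-only regions (13.5% of all, interval 11.5 to 15.7, on 1.64% of the length), a density of 2.83 per Mb against 0.454 per Mb on the rest of chromosome 1. By band, 35 of 862 bands held more treated-only regions than expected from length. The bands with the most were 1p13.2 with 26 regions (17.6 times the expectation, exact binomial test, adjusted p = 1.03e-20), 14q12 with 22 (7.35 times), 1p31.1 with 21 (4.02 times), 1p22.2 with 20 (16.1 times), 1p21.2 with 19 (22.1 times, the highest of these) and 7q21.11 with 17 (5.55 times). Outside chromosome 1, band 16q24.2 held 12 regions in 1.6 Mb, 21.8 times the expectation (exact binomial test, adjusted p = 1.98e-10). Neighbouring regions are not independent, and at 1p13.2 runs of 11 and 5 regions spanned 402 and 198 kb. The p-values by band are therefore too small. At the 144 regions of bands 1p31.1 to 1p12 the median background was 1.38 times the genome background, against 1.03 at the other treated-only regions (permutation p = 5e-05, the smallest that 20000 resamples can give). Their median fold was lower, at 3.88 against 4.32 (permutation p = 5e-05). Both permutations treat neighbouring regions as independent, so their p-values are too small, to an extent not measured. The genome background of the treated list was 2.91 reads, so the background medians lie 0.344 times 2.91 reads apart. The recovered background has the genome background as its lowest value. The ratios are therefore not a measure of copy number.

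**Figure D3:**
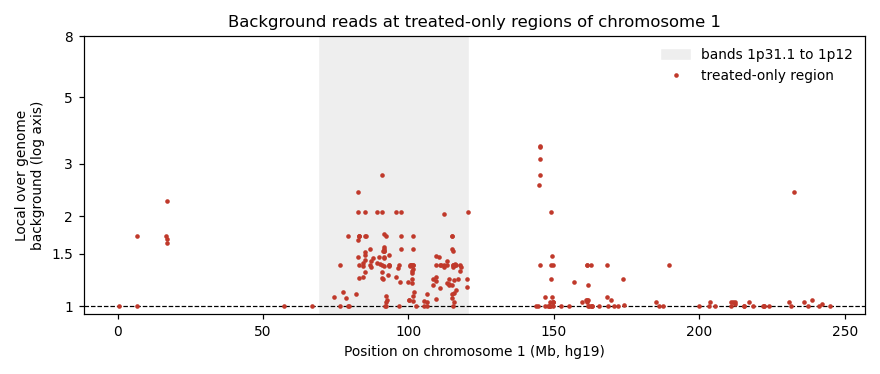
Local background reads over the genome background (log axis) at each treated-only region of chromosome 1, by position in Mb of hg19, with bands 1p31.1 to 1p12 shaded and a dashed line at 1. The median is 1.38 in the shaded bands and 1.03 on the rest of the chromosome, at a genome background of 2.91 reads.

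Along the chromosomes, treated-only and DMSO-only regions both lay in clusters. The median distance from a treated-only summit to the nearest other was 127 kb, against 783 kb by random placement (permutation p = 0.000999, the smallest possible), and for DMSO-only regions it was 132 kb against 2812 kb (permutation p = 0.000999). Counting regions within 10 kb of each other once, the treated-only median was 308 kb. Within 2 Mb of a centromere there were 34 treated-only regions (3.19%, interval 2.22 to 4.43). The median distance of treated-only summits to the chromosome end was 40.7 Mb, against 36.4 Mb by random placement (permutation p = 0.002), and this direction turned for the 403 regions at genome background, with 33.3 Mb (permutation p = 0.304). Pale G-negative bands, which are gene-rich, held 48.2% of treated-only regions against 42.6% by random placement (permutation, adjusted p = 0.00533). With centromeric, stalk and variable heterochromatin bands left out of regions and placements, the shares were 48.6% and 46.1% (permutation p = 0.106), so the call did not hold. The darkest G-positive bands held 16.2% against 15.9% (permutation, adjusted p = 0.853).

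DMSO-only regions lay near centromeres more often than random placement gave. Of the 279, 66 (23.7%, interval 18.8 to 29.1) lay within 2 Mb of a centromere, against 20.4 by random placement (permutation p = 0.002). The median background at these regions was 19.8 times the genome background. Of all 279 DMSO-only regions, bands 16q11.2 and 10q11.21, which lie next to centromeres, held the most, with 15 and 13. These bands span 8.4 and 3.8 Mb, so their regions need not be among the 66. The darkest G-positive bands held 2.87% of DMSO-only regions against 13.4% by random placement (permutation, adjusted p = 0.0032), and pale bands held 57.3% against 42.9% (permutation, adjusted p = 0.0032).

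The 12 most enriched treated-only regions were spread over 7 chromosomes, with folds from 6.21 to 8.67. The first was at 9p11.2 (chromosome 9, 44235061 to 44235559), with a fold of 8.67 and 58 reads at its summit. It was followed by 5p15.33 (chromosome 5, 12973 to 14389, fold 7.90), next to the strongest shared region, 12q24.11 (chromosome 12, 111344390 to 111345418, fold 7.65) and 14q22.3 (chromosome 14, 55955112 to 55956285, fold 7.11). The region at 5p15.33 lay within 5 kb of a DMSO region (11493 to 12491) and would be shared if that distance counted as overlap. Chromosome 1 contributed 3, at 1p21.2 (101719641 to 101720295, fold 6.81), 1p22.3 (87261753 to 87262951, fold 6.51) and 1q23.3 (161423879 to 161423966, fold 6.21). Chromosome 2 contributed 4, at 2q36.3 (230984276 to 230985559, fold 6.64), 2p11.2 (87576893 to 87576975, fold 6.63), 2q35 (216473895 to 216474716, fold 6.48) and 2p13.3 (68675601 to 68676442, fold 6.35). The remaining region was at 3q26.1 (chromosome 3, 162025997 to 162027009, fold 6.64). All but 2 of the 12 were between 499 and 1417 bp wide.

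The 6 most enriched DMSO-only regions had folds from 18.5 to 31.4 in their own list. They lay at 11q25 (chromosome 11, 134946236 to 134946534, fold 31.4), 12q24.33 (chromosome 12, 133839796 to 133841520, fold 23.8), 6p25.3 (chromosome 6, 147827 to 147967, fold 23.8), 1p36.33 (chromosome 1, 568750 to 569323, fold 18.5), 3q11.2 (chromosome 3, 96336701 to 96337087, fold 18.5) and 7p13 (chromosome 7, 45291563 to 45291674, fold 18.5). The regions at 11q25 and 12q24.33 lay 60.2 and 10.5 kb from the chromosome end. The region at 1p36.33 lay next to a DMSO region that is shared (567446 to 568593).

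The fixed gene lists ask whether the breaks fall near loci known for fragility or repeats, here at the level of cytogenetic bands. Bands of common fragile site genes, long genes where chromosomes break under mild aphidicolin, held 52 treated-only summits in 13 of 28 bands, 1.04 times random placement (permutation, adjusted p = 0.834). The highest treated-only fold in such a band was 5.49 in 7q21.11, the band of MAGI2, which held 17 treated-only summits. In 7q36.3, the band of PTPRN2, it was 5.48, below a shared region of fold 5.77. Bands of repeat expansion disease genes held 44 treated-only summits in 12 of 23 bands, 1.57 times random placement (permutation, adjusted p = 0.021), and 1.35 times with placement kept within 10 Mb (permutation, adjusted p = 0.0769). Among all treated regions they held 48, at 1.59 times (permutation, adjusted p = 0.021), and 1.31 times within 10 Mb (permutation, adjusted p = 0.049). Band 16q24.2, with JPH3, held 12 of the 44 treated-only summits, and without it, a choice made after its value was seen, the treated-only list stood at 1.18 times (32 summits, permutation, adjusted p = 0.657). All treated regions were not tested without this band. Counting shared regions too, the highest treated folds in bands of these genes were 12.7 in 21q22.3 with CSTB and 9.13 in 4p16.3 with HTT. Both were at shared regions, 10.1 kb from the chromosome end. These bands held 5 and 1 treated summits, of which 2 and 0 were treated-only. Next were 6.06 in 6q27 with TBP and 5.77 in 6p22.3 with ATXN1, a band with 10 treated-only summits. CSTB encodes cystatin B, HTT huntingtin and TBP the TATA-box binding protein.

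The other lists did not pass the test for an excess of treated-only regions. Summits in their bands stood at 0.176 times random placement for early replicating fragile site genes, at 0.747 for replication stress response genes, at 1.03 for mucin genes, at 0.869 for cancer genes and at 1.11 for olfactory receptors (permutation, adjusted p from 0.657 to 0.998). Among all treated regions the olfactory receptor bands, included as a family with no known role here, stood at 1.33 times (permutation, adjusted p = 0.021), and at 1.21 times with placement kept within 10 Mb (permutation, adjusted p = 0.0629). The bands of replication stress genes with the highest treated folds were 4p16.3 with RNF4 (9.13) and 3q23 with ATR itself (7.22). Both folds were at shared regions, in bands with no treated-only summit. The 4p16.3 region is the one given for HTT, near the chromosome end. Next were 2q35 with SMARCAL1, a fork-remodelling annealing helicase (6.48), and 14q21.2 with FANCM, a DNA translocase of the Fanconi anaemia pathway (5.89). For cancer genes the bands with the highest treated folds were 5q22.2 with APC and 10q26.13 with FGFR2 (5.48 each), 9q34.3 with NOTCH1 (5.27) and 13q14.2 with RB1 (5.19). The band of MUC4 and MUC20 (3q29) led the mucin genes with 7.94 at a shared region 124 kb from the chromosome end (4.42 at its treated-only region). The band of CD83 (6p23, 5.77) was the only early replicating one with a treated summit.

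Among DMSO regions, olfactory receptor bands held 70 summits, 2.57 times random placement (permutation, adjusted p = 0.00699), and 1.69 times with placement kept within 10 Mb (permutation, adjusted p = 0.00699). Mucin gene bands held 18, at 2.62 times (permutation, adjusted p = 0.00699), and 1.37 times within 10 Mb (permutation, adjusted p = 0.22). Common fragile site bands held 3 DMSO summits, 0.234 times random placement, fewer than chance placed there (1-sided permutation test for a deficit, adjusted p = 0.014), and 0.411 times with placement kept within 10 Mb, where the deficit was not tested. The difference between the lists in these shares was not tested.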

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

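All tests in this part were chosen after the files were seen, and the prediction for the pileup ceiling was written before its result was computed. The DMSO list held 52 of its 381 regions (13.6%, exact interval 10.4 to 17.5) on sequences outside chromosomes 1 to 22, X and Y, and the treated list held 10 of 1133 (0.883%, interval 0.424 to 1.62). These lay outside the comparisons of the report and drew attention because the control condition held more. Of the 52, 4 were on mitochondrial DNA (highest fold 2.14, background 50.1 times the genome background) and 48 on unplaced or unlocalised sequences.

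DMSO-only regions near centromeres and on unplaced or mitochondrial sequence formed 1 pattern of 117 regions that the treated list lacks. Repeat copies collapsed into few positions of the assembly are a candidate explanation for their presence, since the median input background there was 18.0 times the genome background, against 1.00 at the other 213 DMSO-only regions. For their absence after treatment, a ceiling on the pileup may contribute. The highest DMSO summit held 156 reads, which is 1 read per position and strand over the 78 bp fragment, and the treated pull-down was scaled by 0.567. The treated input at these regions was not measured, so its ratio to the genome background was assumed equal to that of the DMSO list. On that assumption, 59 of the 117 regions (50.4%, interval 41.0 to 59.8) could not have reached the lowest significance of the treated list at that ceiling. Of the other 213, 15 (7.04%) could not. These 213 were set apart by position alone and can include repeats farther from centromeres. The test therefore leaves open whether the ceiling accounts for most of the pattern, it does not reach the remaining 58, and a true loss of breaks at these repeats after ATRi+APH was not tested.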

How the results depend on the processing

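Matched thresholds, lists without chromosome ends, shuffles avoiding heterochromatin, regions at genome background, shuffles within 10 Mb, and lists without single bands or heterochromatin were added after the files were seen; the others were set before the data were examined. Of 61 alternative values, 36 kept their direction and side of the threshold or, for counts, stayed within 1.5 times, or, for the share of treated regions, within its interval. The list lengths depended most on the threshold. With a −log10 q of at least 10 there were 35 treated and 168 DMSO regions, and with a fold of at least 5 there were 170 treated and 251 DMSO regions. At the same lowest −log10 p the treated count was 119, with DMSO unchanged at 329. At a fold of at least 6.06, the lowest of DMSO peaks at genome background, there were 39 treated and 223 DMSO regions. The overlap passed its test under all 8 alternatives, with 7.09% to 25.5% of DMSO regions shared. The share of treated regions with a counterpart, 5.16% over the whole lists, moved far more with the threshold. It was 71.4% of 35 regions at the stricter −log10 q in both lists, 80% with that threshold in the treated list alone (added after the files were seen), 31.9% of 119 at the same lowest −log10 p and 14.3% of 329 at equal list lengths. With reciprocal 50% overlap it was 2.67%, and without chromosome ends 1.94%. The log2 fold difference of shared regions was 0.0215 without chromosome ends, where the cause is the removal of the subtelomeric regions. The stricter −log10 q left 7 treated-only regions. Their chi-square (22), nearest summit (14457 kb) and distance to the end (51.4 Mb) did not pass 0.05, where fewer regions were tested, while 42.9% on chromosome 1 did (exact binomial p = 0.0143). At genome background the distance to the end turned to 33.3 Mb; the cause was not tested. Shuffles within 10 Mb took the ratios of repeat expansion genes in treated-only (1.35), olfactory receptors in all treated (1.21) and mucin genes in DMSO regions (1.37) out of significance. Without 16q24.2 the repeat expansion ratio was 1.18, and without heterochromatin the pale-band share was 48.6%, neither past the threshold. The local shuffles moved ratios that had not passed to the other side of 1 for fragile site genes (0.82 in treated-only and 0.822 in all treated regions), mucin genes in treated-only (0.938) and early replicating genes in DMSO regions (0.336); the cause was not tested.

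No paired analysis was possible because the labels number the replicates 1 and 2 in both conditions while the deposited lists pool them. Leaving out a replicate and a fit with a replicate block were not run for the same reason. Settings foreseen for sequence composition, for gene positions and for gene bodies with 10 kb around them, and gene-list shuffles within 1 Mb, were not run. The pull-downs differed in depth (mean pileup 1.64 and 5.13 reads), and beyond the number of peaks before selection, what this adds to or takes from either list was not tested.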

Other observations

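All tests in this part were chosen after the files were seen. Peak numbers run along the genome and reach 11612 in the DMSO list and 10154 in the treated list. The deposited lists are therefore taken to be a selection, an inference that the labels do not state. On that reading the numbers bound how many peaks each chromosome held before selection. Before selection, DMSO peaks followed gene density. Over the 22 autosomes, peaks per Mb (midpoint of the bounds) rose with protein-coding genes per Mb (Spearman's rho 0.765, permutation p = 1e-04, the smallest possible, adjusted p = 0.0002; Pearson's r 0.949, p = 1e-04). Without chromosomes 19 and 17, r was 0.721. Chromosome 19 held 19.5 to 19.9 DMSO peaks per Mb and 2.27 to 2.57 treated peaks per Mb. Chromosome X held 0.0773 to 0.167 DMSO peaks per Mb, so it was sparse without treatment too. For treated peaks rho was 0.369 (p = 0.0908) and r was 0.108 (p = 0.662), or 0.375 without those chromosomes. The difference between the lists in rho was 0.396 (permutation of the lists within chromosomes, p = 0.0222), and without chromosomes 19 and 17 it was 0.257 (p = 0.28), so the call did not hold without them.

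Among the selected regions, the band around a DMSO-only region held a median of 6.85 protein-coding genes per Mb, against 5.76 around a treated-only region (difference 1.09, permutation p = 0.002). Random placement, which did not avoid gaps, gave 5.44 for DMSO-only regions (permutation, adjusted p = 0.004) and 5.12 for treated-only regions (permutation, adjusted p = 0.003). For shared regions the median was 9.31, against 4.57 (permutation, adjusted p = 0.003). All sets lay above these placements. Of treated-only regions 0.563% lay in centromeric bands, against 3.29% of their placements. Whether such placements lowered the random medians was not tested, so no excess of gene density is concluded from them. Away from ends and centromeres, the medians of DMSO-only and treated-only regions were 10.4 and 5.76 (difference 4.64, permutation p = 5e-05, the smallest possible). Regions of the same band share 1 gene density, and these tests count them as independent. The 1065 treated-only regions lay in 353 bands and the 279 DMSO-only regions in 142. The p-values for gene density are therefore too small, to an extent not measured.

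Runs of at least 5 treated-only regions with gaps of at most 100 kb occurred 9 times and held 58 of the 1065 regions (5.45%), where random placement gave 0.02 such runs on average (permutation p = 0.000999, the smallest possible). DMSO-only regions formed 8 such runs with 64 of 279 regions (22.9%), against 0.001 on average by random placement. Of the treated-only runs, 7 were on chromosome 1. The run with the most regions was at 1p13.2, with 11 over 402 kb (114921015 to 115322867), followed in number of regions by 1p22.2 with 8 over 161 kb (91497919 to 91659029), and 7 each at 1p21.2 (101573773 to 101720295) and 1q23.3 (161423879 to 161584535). Outside chromosome 1, 5 regions stood within 2.74 kb at 2q34 (209040525 to 209043268) and 5 within 109 kb at 5q35.3 (177522386 to 177631625). Background at the 2q34 run was 1.00 times the genome background, and it was 1.53 times at the run of 8 at 1p22.2.

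The first pattern weighed is the longer treated list. The peak numbers did not show more peaks passing the caller in the deeper treated pull-down. On chromosomes 1 to 22 with their unlocalised sequences, which hold all treated regions of the comparisons, at most 10146 treated peaks stood against at least 11473 DMSO peaks before selection. The ratio was at most 0.884. Treated peaks on X and Y before selection have no such bound. The caller settings of both lists are not given. Whether depth carried more treated peaks past the selection was not tested, so an effect of depth on the list lengths stays open. A lower selection floor in the treated list could account for the order of the lengths, because 119 treated regions reach the lowest −log10 p of the DMSO list, against 329 DMSO regions. An increase in the number of break sites with ATRi+APH stays open, as the pooled lists cannot test it.

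The second pattern is the concentration of treated-only regions in bands 1p31.1 to 1p12. Higher local input coverage, as from extra copies of this segment, is a candidate explanation, since the median background there lay 0.344 genome backgrounds above that of the other treated-only regions. At a genome background of 2.91 reads this is a difference of 0.344 times 2.91 input reads, and copy number was not measured. The median fold in these bands was 3.88, against 4.32 at the other treated-only regions. A cause present without treatment cannot be told apart from one that needs it, because the DMSO peaks before selection were between 0.949 and 3.11 times as dense in these bands as on the rest of chromosome 1. For treated peaks this ratio was 3.76 to 3.93. A response of this segment to ATRi+APH remains an untested biological explanation.

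Across the 21 chromosomes with at least 10 treated-only regions, density rose with the percentage of these regions above the genome background (Spearman's rho 0.627, permutation p = 0.0037; Pearson's r 0.664, p = 0.0008). Without chromosomes 13 and 14, whose percentages lay farthest from the median, r was 0.622. Chromosome 1, the densest at 0.939 per Mb, was kept there, so its weight was not tested. Regions at 1.03 times the genome background, the median of treated-only regions, count as above it, so the percentage partly reflects small steps.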
